A study of Homo sapiens with 12 samples.

How the data were processed

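The data are 12 libraries of total RNA from ES-2 cells, 3 each for control siRNAs and for siRNAs against IGF2BP1, IGF2BP2 and IGF2BP3, with group and replicate number taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, depleted of ribosomal RNA, fragmented and reverse transcribed with random hexamers, and paired reads were sequenced. A pool held up to 10 libraries per the labels' protocols, and which library was in which pool is not given in the sources used here. Per the submitters' processing notes, adapters were removed with cutadapt 1.6, reads were mapped with TopHat2 2.0.13 to the hg19 build and counted with featureCounts 1.4.6, and edgeR 3.12 was used; filters, strand settings and the annotation release are not given in the sources used here. The treatment protocol in the labels speaks of parental cells, while the titles and the siRNA labels place each library in its group.

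The deposited table holds, per the file headers, FPM for each library, a signal normalized by the authors, with 57865 features of which 92 are ERCC spike-in RNAs. Values in each library were whole multiples of what 1 read is worth, 0.108 to 0.243 FPM; within a tolerance of 0.01, 100% of values came out whole. Recovered totals were 3299360 to 11304060 reads, and column sums of 800026 to 1219058 FPM correspond to a library size scaled by a factor of 0.82 to 1.25. Per the file headers, the authors also gave a log2 fold change and an FDR, a p-value adjusted for multiple tests, for each knockdown against control; these log2 and FDR columns are quoted only as the authors' deposited table. Every mitochondrially encoded gene is listed at 0. Gene symbols were taken from GENCODE release 29 by identifier for 52338 features and by symbol for 1945, and 3490 kept the name in the table.

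The gene lists, miRNA families and rule for named genes were fixed before the data were examined. The test fixed at the same time was edgeR's quasi-likelihood test on counts. The table holds normalized values, so the main test was limma 3.58.1 with a mean-variance trend on log2(FPM + 1), which understates the change of low genes, over all 12 libraries with 1 coefficient per group. Recovered reads served to filter genes with filterByExpr (minimum count 10), which left 13782 genes without the spike-ins. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called below an adjusted p of 0.05. edgeR 4.0.16 on the recovered reads, an added alternative, called 1388 genes in siI1, 185 in siI2 and 1370 in siI3 against siC, of which 1094, 146 and 1192 were also called by limma. R 4.3.3 and DESeq2 1.42.0 were also used. The limma test was tested on simulated data, 5 sets of siI1 against siC over 13782 genes with 200 changed genes. It recovered 1.5%, 14.6% and 70% of genes changed by 1.5, 2 and 4-fold, with 3.2 false calls among 61 on average. With a GC trend added to siC replicates 1 and 3 only, 14.6 of 72.8 calls were false on average. It was 4.6 of 61.2 after the correction described next (13575 genes). A trend shared by a whole group was not simulated.

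The correction for GC content and length, chosen after the data were seen, subtracted from each library a single loess surface (span 0.5) fitted to its deviations from the gene means over GC content and length of the longest annotated transcript. It was possible for 13575 genes (98.5%). Gene lists with at least 5 measured members (22 of 26) were tested with camera (preset correlation 0.01) in a two-sided test on log2(FPM + 1), where voom values of counts had been foreseen, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Sites were 7mers that pair with miRNA bases 2 to 8 in the longest annotated 3' UTR per gene of GENCODE release 29, with 17 broadly expressed and 7 tissue-restricted families, adjusted over all 72 tests. Named genes were the IGF2BPs, HMGA2, LIN28B and MYC; for each knockdown the 10 largest increases and 10 largest decreases among called coding or lncRNA genes with a mean of at least 5 FPM in the higher group and no overlap between groups; up to 4 called members per list; up to 6 genes per direction called in all 3 knockdowns; and 5 per direction in each direct comparison. Chance overlap was simulated 50 times, with all 12 libraries, controls included, drawn as independent noise per gene. Counts of 0 to 3 reads lie at or under the floor, and floors and intervals cover counting error only.

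The alternatives were other tools (DESeq2, edgeR, voom), scaling factors, filters, a minimum fold, the replicate number as a block, protein-coding genes only, only the 6 libraries compared, each library left out in turn, other pseudocounts (0.25 and 4), and the correction for GC content and length. The spike-ins were left out of library sizes and tests, and strand and genome positions were not used.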

Results

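Total RNA was sequenced from ES-2 cells, an established line derived from an ovarian cancer, treated with control siRNAs (siC) or with siRNAs against IGF2BP1 (siI1), IGF2BP2 (siI2) or IGF2BP3 (siI3). The 3 proteins bind mRNAs and influence their stability, transport and translation. Each of the 4 groups held 3 libraries, made from RNA depleted of ribosomal RNA and primed with random hexamers. Levels are in FPM, the depth-normalized fragment unit of the deposited table. The libraries held from 3299360 reads in siI2 replicate 3 to 11304060 reads in siC replicate 2, and 3 reads corresponded to 0.32 to 0.73 FPM. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples.

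No 2 libraries of a group were as close as repeat sequencing of 1 library would be, with a chi-square per degree of freedom of 8.4 to 88.6 over the 12 pairs of replicates. The signal recognition particle RNA RN7SL took 13.8% ± 2.25 of reads in siC (SD, n = 3), 20.3% ± 4.85 in siI1, 25.6% ± 2.5 in siI2 and 25.5% ± 4.58 in siI3. The spliceosomal U1 RNA took 15.9% ± 6.35, 7.86% ± 5.68, 5.89% ± 3.9 and 4.91% ± 6.42 of reads in the same order. A gene's level followed the GC content of its transcript differently between libraries. For each library, the deviation of genes from their mean over all libraries was regressed on GC content. The slope was -0.46 and -0.43 (log2 per 10 points of GC) in siC replicates 1 and 3 but 0.02 in siC replicate 2. These slopes are relative to that mean, so a flat slope does not show a library free of GC bias. The 9 knockdown libraries lay between -0.09 and 0.21. Across genes, which are not independent replicates, the log2 fold change against siC correlated with transcript GC content at a Spearman's rho of 0.60 for siI1, 0.60 for siI2 and 0.55 for siI3. It was 0.09, 0.03 and -0.05 for the 3 comparisons between knockdowns. A fit corrected for GC content and transcript length, chosen after the data were seen, is therefore given beside each comparison.

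**Figure D1:**
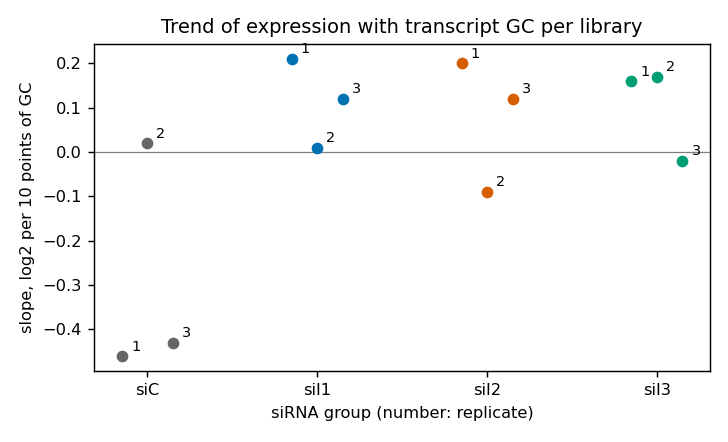
Slope against transcript GC content (log2 per 10 points of GC, y axis) of each gene's deviation from its mean over the 12 libraries. Each point is a library, by siRNA group (x axis), with the replicate number beside it. siC replicates 1 and 3 lie at -0.46 and -0.43, and the other libraries between -0.09 and 0.21.

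Each siRNA lowered the mRNA it was aimed at. IGF2BP1 was at 43.9 ± 4.52 FPM in siC (SD, n = 3) and 11 ± 0.538 FPM in siI1, which is 25.2% of siC (log2 fold change -1.89, SE 0.18, limma adjusted p = 1.19e-05). IGF2BP2 was at 80 ± 4.72 FPM in siC and 13.4 ± 5.1 FPM in siI2, which is 16.8% of siC (-2.55, SE 0.22, limma adjusted p = 3.45e-05). IGF2BP3 was at 23.5 ± 5.18 FPM in siC and 4.52 ± 1.76 FPM in siI3, which is 19.2% of siC (-2.19, SE 0.28, limma adjusted p = 0.000658). The targeted gene had its lowest 3 of the 12 values in the 3 libraries of its own knockdown in every case. IGF2BP3 was at 64.7% of siC in siI1 and 63.5% in siI2, but neither difference passed the test (limma adjusted p = 0.19 and 0.2, n = 3), and the corrected log2 fold changes were -0.09 and -0.14. The other two paralogs did not pass in any other knockdown, with limma adjusted p-values from 0.262 to 0.684 (n = 3). Among the mRNAs named for every comparison, the let-7 target HMGA2 (29.2 ± 6.12 FPM in siC) and the transcription factor MYC (293 ± 68 FPM) did not pass in siI1, siI2 or siI3, with limma adjusted p-values of 0.249 to 0.995. The let-7 repressor LIN28B lay at 0.387 to 0.71 FPM on average, from 0 to 9 reads per library, too few reads to compare.

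**Figure D2:**
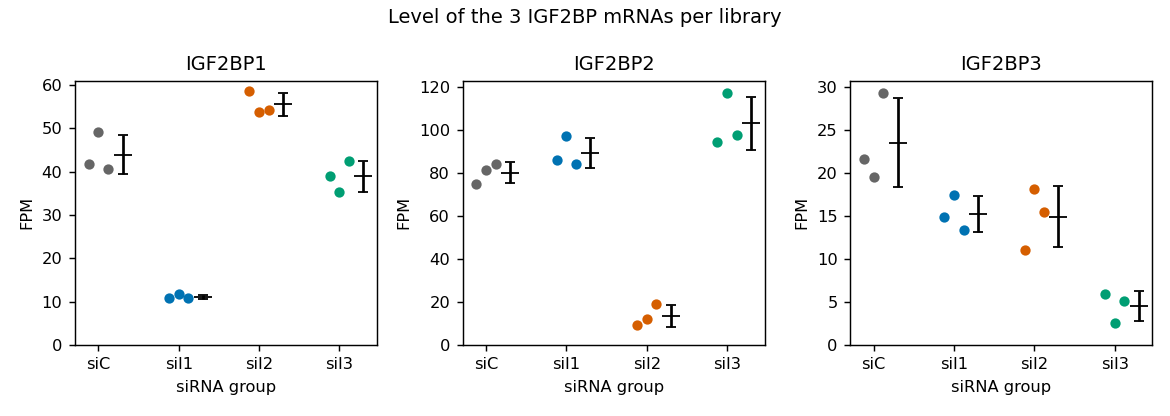
Level of IGF2BP1, IGF2BP2 and IGF2BP3 (FPM, y axis) in each library by siRNA group (x axis); points are libraries, and the horizontal mark and bar give the mean and SD of 3. The targeted mRNA is lowest in its own knockdown, at 11, 13.4 and 4.52 FPM on average.

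Knockdown of IGF2BP1 addressed which mRNAs depend on this protein in a cell where it is thought to protect oncogenic transcripts from miRNAs. COL1A1, the alpha 1 chain of type I collagen, rose from 93.5 ± 16.5 FPM in siC to 750.4 ± 53.5 FPM in siI1 (SD, n = 3; log2 fold change 3.00, SE 0.26, limma adjusted p = 6.2e-06). The matrix glycoprotein SPARC went from 626.4 ± 113 to 2308 ± 16.4 FPM (1.90, SE 0.21, limma adjusted p = 6.99e-05), and the secreted guidance cue SLIT3 from 13.5 ± 2.03 to 98.2 ± 1.45 FPM (2.79, SE 0.19, limma adjusted p = 6.05e-07). The chemokine CXCL8 fell from 134.5 ± 22.3 to 13.2 ± 3.2 FPM (-3.27, SE 0.52, limma adjusted p = 0.00135), and the collagenase MMP1 from 1748 ± 363 to 337.7 ± 48.5 FPM (-2.36, SE 0.40, limma adjusted p = 0.00234). The serine protease inhibitor SERPINB2 went from 394.6 ± 61.8 to 43.6 ± 3.32 FPM (-3.14, SE 0.18, limma adjusted p = 1.05e-07). The other genes with the largest increases were the immune checkpoint receptor VSIR (3.46), the metalloprotease ADAMTS15 (2.86), the matrix protein EFEMP1 (2.67), RARRES3 (2.54), AL590004.3 (2.51), RP11.463P17.1 (2.51), ARNT2 (2.47) and the platelet-derived growth factor receptor PDGFRB (2.46). Those with the largest decreases were ESM1 (-3.01), CCDC6 (-2.87), the angiopoietin ANGPT2 (-2.50), EIF2A (-2.44), NRIP3 (-2.43), AC002454.1 (-2.41) and SERPINB7 (-2.36). RP11.463P17.1 had no GC value, and the other 19 of these 20 genes were also called after the GC and length correction. EIF2A and AC002454.1 lost the call without siC replicate 1, siC replicate 3, siI1 replicate 1 or siI1 replicate 3, and the other 18 kept it in each of the 6 fits.

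In siI1, 9 of the 22 gene lists tested were called by camera with its preset correlation, and none stayed called with an estimated correlation. After the GC and length correction each of the 9 was still called with the preset correlation (camera adjusted p = 0.00022 to 0.0346), and again none with an estimated one. Interferon-stimulated genes rose as a list (adjusted p = 0.0235; adjusted p = 0.195 with an estimated correlation), with 5 of 29 measured members up, 1 down and 23 not passing. IFITM1, a membrane protein that restricts virus entry, rose by 2.02 (limma adjusted p = 0.000491), IFITM3 by 1.14 (0.00416) and the transcription factor IRF1 by 1.17 (0.00809), the last lost without siC replicate 1, siC replicate 3 or siI1 replicate 1. The mesenchymal list rose (adjusted p = 0.0364; adjusted p = 0.199 with an estimated correlation), with 7 of 24 up and 2 down, among them the collagen gene COL5A1 (1.88). The epithelial list rose too (adjusted p = 0.00879; adjusted p = 0.195 with an estimated correlation), with 3 of 10 up, of which the keratin KRT8 went up by 1.73. TGF-beta targets rose (adjusted p = 0.00801; adjusted p = 0.311 with an estimated correlation), with 5 of 20 up and 0 down, among them the inhibitory SMAD6 (2.03). Cholesterol synthesis rose (adjusted p = 0.00409; adjusted p = 0.311 with an estimated correlation), with 5 of 23 up, among them its regulator SREBF2 (1.13) and the lanosterol synthase LSS (1.18). Glycolysis and hypoxia genes rose (adjusted p = 0.00879; adjusted p = 0.391 with an estimated correlation), with 4 of 27 up, among them BNIP3 (0.99). ERK feedback genes fell (adjusted p = 0.00409; adjusted p = 0.311 with an estimated correlation), with 5 of 23 down, among them the EGF receptor ligand HBEGF (-1.35), the receptor kinase inhibitor SPRY2 (-1.21) and the ERK phosphatase DUSP5 (-0.98). Genes of the unfolded protein and integrated stress response fell (adjusted p = 0.00617; adjusted p = 0.308 with an estimated correlation), with 7 of 34 down and 1 up, among them the asparagine synthetase ASNS (-1.86). Genes of G2 and mitosis fell (adjusted p = 0.000991; adjusted p = 0.311 with an estimated correlation), with 3 of 34 down, of which UBE2C (-0.77, corrected -0.63) was also called after correction while HMMR and TTK were not. All 3 lost the call without siC replicate 1, siC replicate 3, siI1 replicate 1 or siI1 replicate 3, and UBE2C and TTK also without siI1 replicate 2. Adjusted over the list alone, 5 interferon genes were up and 2 down, 7 mesenchymal genes up and 6 down, 3 epithelial genes up, 7 TGF-beta targets up and 1 down, and 6 cholesterol genes up. In the same way, 5 glycolysis genes were up, 7 ERK feedback genes down, 10 stress response genes down and 1 up, and 11 G2 and mitosis genes down. Without siC replicate 2 the adjusted p was 0.0853 for the interferon list, 0.0634 for ERK feedback and 0.0853 for the mesenchymal list, and without siI1 replicate 2 it was 0.0502 and 0.0578 for the interferon and mesenchymal lists. Histone genes were called up without siC replicate 2 (0.00105) and without siI1 replicate 2 (0.0429).

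In all, 1128 of 13782 genes tested were called in siI1, 519 up and 609 down (46% up; limma, n = 3 per group), against 531 up and 407 down after the GC and length correction (56.6% up), with 628 called in both. The share up was 56.7% with RLE factors and 57.9% with upper-quartile factors. The count was 268 without siC replicate 1, 2602 without siC replicate 2, 290 without siC replicate 3, 299 without siI1 replicate 1 and 332 without siI1 replicate 3. Of the 91 called genes that the naming rule gave, 47 lost the call without siC replicate 1 (limma adjusted p 0.0528 to 0.212), 46 without siC replicate 3 (0.0505 to 0.226), 44 without siI1 replicate 1 (0.0551 to 0.189), 18 without siI1 replicate 2 (0.0512 to 0.0906) and 42 without siI1 replicate 3 (0.0535 to 0.164). Of the genes given above from the lists, LSS and SREBF2 are among these, while COL5A1, SPARC, KRT8, SMAD6, BNIP3, HBEGF, SPRY2, DUSP5, ASNS, IFITM1 and IFITM3 kept the call in each of the 6 fits and after the correction.

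Knockdown of IGF2BP2 asked the same question for the second paralog, and fewer genes passed. COL1A1 again rose, from 93.5 ± 16.5 FPM in siC to 358.4 ± 151 FPM in siI2 (SD, n = 3; log2 fold change 1.86, SE 0.26, limma adjusted p = 0.00248). The collagen prolyl hydroxylase P3H2 went from 6.22 ± 1.56 to 27.0 ± 3.86 FPM (1.97, SE 0.26, limma adjusted p = 0.00248), and QPRT, an enzyme of NAD synthesis from tryptophan, from 11.4 ± 2.25 to 46.2 ± 11.7 FPM (1.92, SE 0.25, limma adjusted p = 0.00248). The TGF-beta receptor TGFBR2 fell from 49.2 ± 8.97 to 15.3 ± 2.83 FPM (-1.62, SE 0.23, limma adjusted p = 0.00311), and the stromelysin MMP3 from 7.26 ± 2.97 to 0.439 ± 0.585 FPM (-2.54, SE 0.38, limma adjusted p = 0.00428). The siI2 mean of MMP3 lies under the floor of 3 reads (0.55 to 0.73 FPM in siI2), so the size of its change is uncertain. The other genes with the largest increases were the neonatal Fc receptor FCGRT (1.98), FAM131B (1.91), the prostaglandin synthase PTGS1 (1.70), the kinesin KIF5C (1.67), CORO1A (1.64), GGT5 (1.62) and SYT11 (1.62). Besides IGF2BP2 and MMP3, those with the largest decreases were BTG3 (-2.22), the sphingolipid enzyme SPTLC3 (-2.12), LCLAT1 (-2), RND3 (-2), VRK1 (-1.98), HBP1 (-1.91), NR1D2 (-1.81) and ARRDC3 (-1.76). RND3, VRK1, HBP1, NR1D2 and ARRDC3 were not called after the GC and length correction, with adjusted p-values of 0.0514 to 0.106 (limma). COL1A1, P3H2, QPRT, SYT11, MMP3, LCLAT1, SPTLC3 and IGF2BP2 kept the call in each of the 6 fits that left out 1 library, as did TGFBR2 and the matrix protein THBS1 (1.11, corrected 1.35).

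In siI2, 5 of 22 lists were called by camera. All but the other RNA-binding proteins stayed called after the GC and length correction (camera adjusted p = 0.00116 to 0.00987), and none with an estimated correlation added. Genes of G2 and mitosis fell (adjusted p = 0.00138; adjusted p = 0.551 with an estimated correlation), with 1 of 34 members down, the cytokinesis protein ANLN (-1.52), which was not called after correction (limma adjusted p = 0.0713). Other RNA-binding proteins fell (adjusted p = 0.0412; adjusted p = 0.491 with an estimated correlation) with 0 of 31 members called, and this was lost after the GC and length correction (adjusted p = 0.433). The mesenchymal list rose (adjusted p = 0.0214; adjusted p = 0.277 with an estimated correlation), with 2 of 24 up, of which PDGFRB went up by 1.62. Cholesterol synthesis rose (adjusted p = 0.00182; adjusted p = 0.551 with an estimated correlation) with 0 of 23 members called, and histone genes rose (adjusted p = 0.00138; adjusted p = 0.738 with an estimated correlation) with 0 of 53 called. Adjusted over the list alone, 9 G2 and mitosis genes were down and 1 up, 1 RNA-binding protein gene was down, 7 mesenchymal genes were up and 3 down, 5 cholesterol genes were up and 0 histone genes were called. The list of other RNA-binding proteins was not called without siC replicate 2 (adjusted p = 0.0567), siC replicate 3 (0.0967), siI2 replicate 1 (0.144) or siI2 replicate 2 (0.0728). The mesenchymal list was not called without siC replicate 2 (adjusted p = 0.0694), nor the histone list without siC replicate 3 (0.157) or siI2 replicate 1 (0.206), and 3 lists were called in all without either of these last 2 libraries. ERK feedback genes were called down without siC replicate 1 (0.0234). The interferon list had a median of -0.28 in siI2 and was not called by camera (adjusted p = 0.312). Adjusted over the list alone, 4 of its 29 measured members were down, and fry called the list down (fry adjusted p = 0.00499).

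In all, 208 genes were called in siI2, 79 up and 129 down (38% up; limma, n = 3 per group), against 110 up and 82 down after the correction (57.3% up), with 112 called in both. The majority turned under other scalings, with 60.1% up for RLE factors and 62.4% for upper-quartile factors, and edgeR called 115 up and 70 down. The count was 36 without siC replicate 1, 1572 without siC replicate 2, 28 without siC replicate 3, 37 without siI2 replicate 1, 1414 without siI2 replicate 2 and 63 without siI2 replicate 3. Of the 42 called genes that the naming rule gave, 29 lost the call without siC replicate 1 (limma adjusted p 0.0528 to 0.259), 29 without siC replicate 3 (0.0524 to 0.268), 28 without siI2 replicate 1 (0.0501 to 0.181) and 23 without siI2 replicate 3 (0.0503 to 0.164). The genes lost include BTG3, FAM131B, RND3, VRK1, HBP1, NR1D2, ARRDC3, ANLN and PDGFRB without any of the 4. When each of the 12 libraries was left out in turn, VRK1, HBP1, NR1D2, ARRDC3 and ANLN were called in 3 of the 12 fits. BTG3, FAM131B, RND3 and PDGFRB were called in 8. GGT5 was lost without siC replicate 1, siC replicate 3 or siI2 replicate 1, and CORO1A without siC replicate 1 or siI2 replicate 1. KIF5C was lost without siC replicate 1, and FCGRT and PTGS1 without siC replicate 3.

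After knockdown of IGF2BP3 the gelatinase MMP2 fell from 67.8 ± 7.15 FPM in siC to 15.4 ± 2.53 FPM in siI3 (SD, n = 3; log2 fold change -2.07, SE 0.18, limma adjusted p = 3.31e-05). The urokinase PLAU went from 369.3 ± 60.3 to 110.2 ± 20.7 FPM (-1.74, SE 0.20, limma adjusted p = 0.000275) and the tissue plasminogen activator PLAT from 1006 ± 141 to 319.8 ± 61.4 FPM (-1.66, SE 0.21, limma adjusted p = 0.000478). The interferon-induced IFI6 went from 10.3 ± 0.7 to 1.25 ± 0.257 FPM (-2.33, SE 0.34, limma adjusted p = 0.00177), and the leukocyte adhesion receptor VCAM1 from 9.01 ± 2.02 to 0.576 ± 0.0533 FPM (-2.65, SE 0.43, limma adjusted p = 0.00347). The endothelial proteoglycan ESM1, lower in siI1, rose from 10.1 ± 3.65 to 38.9 ± 5.31 FPM (1.89, SE 0.28, limma adjusted p = 0.00177). The other genes with the largest decreases were RPS24 (-3.59), RPL9P8 (-3.19), AC099850.3 (-3.17), AC124067.2 (-2.78), COX7B (-2.72), LINC01425 (-2.68), DARS (-2.65), AC002454.1 (-2.65) and RPL35A (-2.65). Those with the largest increases were the neuronal immediate early gene ARC (2.16), the neuropeptide precursor VGF (2.07), the matrix protein CCDC80 (1.99), VAMP4 (1.96) and 5 listed copies of the DUX4 family (1.88 to 2.07). The DUX4 copies are near identical and RPL9P8 is a processed copy of a ribosomal protein gene, so reads could be split between loci and these 6 values are uncertain. COX7B, DARS and RPL35A were not called after the GC and length correction (limma adjusted p = 0.0626, 0.0626 and 0.0565), and the 6 uncertain genes had no GC value. ESM1, VCAM1, ARC, VGF, CCDC80, VAMP4 and AC124067.2 kept the call in each of the 6 fits that left out 1 library.

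In siI3, 4 of 22 lists were called by camera. The interferon response fell (median log2 fold change -0.65, adjusted p = 0.000335) and was the only list in the 3 comparisons with siC that stayed called with an estimated correlation (adjusted p = 0.038), also after the GC and length correction (adjusted p = 0.0166). Of its 29 measured members, 4 were down and 25 did not pass, and 7 were down adjusted over the list alone. Besides IFI6, these were the ADP-ribosyltransferase PARP14 (-1.28), lost without siC replicate 1, the interferon signalling factor STAT2 (-0.98), lost without siC replicate 3, and the immunoproteasome subunit PSMB9 (-1.14), lost without siC replicate 1, siC replicate 3 or siI3 replicate 2 and after correction (limma adjusted p = 0.0984). Genes of invasion, adhesion and proteolysis fell (adjusted p = 0.0032; adjusted p = 0.0658 with an estimated correlation), with 9 of 30 down and 2 up, and 13 down and 3 up adjusted over the list alone. The integrin ITGB5 was lower by -1.27, beside MMP2, PLAU and PLAT. Genes of G2 and mitosis fell (adjusted p = 0.000335; adjusted p = 0.566 with an estimated correlation), with 9 of 34 down and 19 down adjusted over the list alone, among them KIF20A (-1.24) and TPX2 (-1.20). After the GC and length correction 3 of them were down, and the median went from -0.80 to -0.38. The list stayed called down after it (camera adjusted p = 0.00197), but not with an estimated correlation (0.27). Histone genes rose (median 0.45, adjusted p = 1.55e-05; adjusted p = 0.838 with an estimated correlation), with 0 of 53 members called by either adjustment. Each of the 4 lists stayed called in every fit that left out 1 library. Single genes of lists that did not pass included the matrix protein TGFBI (-2.12), THBS1 (-1.39), fibronectin FN1 (-1.19), the kinase PLK2 (-1.92) and the YAP target ANKRD1 (-2.28), which fell, and tenascin TNC (1.30) and the chemokine CXCL1 (1.21), which rose. These 7 genes, MMP2, PLAU, PLAT, IFI6 and ITGB5 kept the call in each of the 6 fits and after correction.

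In all, 1460 genes were called in siI3, 317 up and 1143 down (21.7% up; limma, n = 3 per group), against 366 up and 572 down after the correction (39% up), with 635 called in both. The share up was 34.5% with RLE factors and 44% with upper-quartile factors. The count was 89 without siC replicate 1, 2824 without siC replicate 2, 111 without siC replicate 3, 215 without siI3 replicate 1, 156 without siI3 replicate 2 and 2742 without siI3 replicate 3. Of the 89 called genes that the naming rule gave, 66 lost the call without siC replicate 1 (limma adjusted p 0.0504 to 0.238), 62 without siC replicate 3 (0.0551 to 0.194), 51 without siI3 replicate 1 (0.0559 to 0.168), 55 without siI3 replicate 2 (0.051 to 0.177), 4 without siI3 replicate 3 (0.052 to 0.0758) and 1 without siC replicate 2 (0.0639). They include RPS24, RPL9P8, COX7B, LINC01425, DARS, AC002454.1, RPL35A, KIF20A and TPX2 without siC replicate 1, siC replicate 3, siI3 replicate 1 or siI3 replicate 2. AC099850.3 was lost without siC replicate 1, siC replicate 3 or siI3 replicate 2. The 5 DUX4 copies were lost without siC replicate 1 or siC replicate 3, 4 of them also without siI3 replicate 1 and 2 also without siI3 replicate 3.

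Several lists were not called by camera in any knockdown against siC before correction. The fry calls for let-7 targets, IGF2BP1-associated mRNAs and the miRNA pathway machinery are given below with the alternatives. The let-7 targets had a median log2 fold change of -0.08, -0.20 and -0.20 in siI1, siI2 and siI3 (adjusted p = 0.44, 0.695 and 0.291), and 3, 1 and 6 of their 31 measured members were called, of which 3, 1 and 2 were also called after the GC and length correction. The corrected medians were 0.01, -0.06 and -0.05. THBS1, among them, was called in each knockdown, up in siI1 (1.24) and siI2 (1.11) and down in siI3. mRNAs described as IGF2BP1-associated had medians of -0.04, -0.02 and -0.13 (adjusted p = 0.338, 0.764 and 0.759), and in siI1 FSCN1 was up (0.98) while SRF (-1.02), SIRT1 (-1.15) and KCNMA1 (-0.75) were down among 20 measured. The call of SRF was lost without siC replicate 3, and those of FSCN1, SIRT1 and KCNMA1 without siC replicate 1, siC replicate 3 or siI1 replicate 3. FSCN1 and SIRT1 also lost it without siI1 replicate 1, and SIRT1 and KCNMA1 without siI1 replicate 2. SIRT1 and KCNMA1 were not called after the correction (limma adjusted p = 0.193 and 0.0599). In siI3, 4 members were down (BTRC, CD44, ABCB1 and CTNNB1) and 1 was up (PDLIM7), of which BTRC (-1.09, corrected -0.79) was also called after correction. BTRC lost the call without siC replicate 1 or siC replicate 3. The miRNA pathway machinery had medians of -0.22, -0.43 and -0.39, and of 0.02, -0.12 and -0.06 after correction (adjusted p = 0.246, 0.109 and 0.247 before). In siI3 5 of 22 members were down and 1 up, and 9 down and 1 up adjusted over the list alone. After the correction 4 members were down and 1 up in siI3, and 5 were called in both fits. The Argonaute AGO1 (-0.96) and the deadenylation scaffold CNOT1 (-1.55) were down and AGO2 (0.63) was up, with AGO1 and CNOT1 lost without siC replicate 1, siC replicate 3, siI3 replicate 1 or siI3 replicate 2. The machinery list was called down in siI2 without siC replicate 2 (adjusted p = 0.0466) and without siI2 replicate 3 (0.0144). Inflammatory cytokines and NF-kB genes had medians of -0.13, 0.10 and 0.15 (adjusted p = 0.168, 0.16 and 0.247). After the GC and length correction this list was called down in siI1 (median -0.33, adjusted p = 0.0209; adjusted p = 0.159 with an estimated correlation). The adjusted p-values in the same order were 0.523, 0.833 and 0.759 for G1/S genes, 0.975, 0.667 and 0.759 for p53 targets, and 0.109, 0.854 and 0.247 for YAP/TEAD and SRF targets. They were 0.935, 0.464 and 0.247 for cytosolic ribosomal proteins, 0.246, 0.459 and 0.871 for neural markers, and 0.409, 0.171 and 0.936 for RNA quality markers. The median and the mean had opposite signs in siI1 for G1/S genes and ribosomal proteins, and in siI3 for G1/S genes, p53 targets, TGF-beta targets, mesenchymal, neural and RNA quality genes. In siI2 the medians of the IGF2BP1-associated mRNAs (-0.02), G1/S genes (-0.03) and p53 targets (-0.02) lay below 0 while camera gave the direction up.

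The 3 knockdowns shared 10 genes up and 18 down against siC. The 6 with the largest smallest increase were CCDC80, the ion channel TRPM2, AEBP1, the let-7 host gene MIRLET7BHG, TXNDC5 and GDPD5, and CCDC80 rose by 1.21 in siI1, 1.28 in siI2 and 1.99 in siI3 (limma adjusted p = 0.0027, 0.00711 and 0.00013, n = 3). The 6 with the largest smallest decrease were POPDC3, RSL24D1, FCF1, YWHAZ, ATP10D and ZNF792, and ZNF792 fell by 1.03, 1.21 and 1.35 (limma adjusted p = 0.0326, 0.0424 and 0.0126, n = 3). CCDC80 lost its call in siI2 without siC replicate 3. ZNF792 lost it in each knockdown without siC replicate 1 or siC replicate 3, in siI1 without siI1 replicate 1 or 3, in siI2 without siI2 replicate 1 or 3, and in siI3 without siI3 replicate 1 or 2. CCDC80, TXNDC5 and ZNF792 were also called in all 3 knockdowns after the GC and length correction, and the other 9 of these 12 genes were not. Over the 12 fits that each left out 1 library, TXNDC5 was called in 7 for siI1, 3 for siI2 and 12 for siI3. Independent lists of these sizes would share 0.07 genes up and 0.47 down, and simulated unchanged groups with 3 simulated controls in common shared 0. The simulation drew every library as independent noise per gene, without the GC trends of the real controls. Few genes could be called in it, so its 0 was close to fixed in advance. siI1 and siI2 shared 46 up and 36 down (3.0 and 5.7 for independent lists), siI1 and siI3 shared 58 up and 206 down (11.9 and 50.5), and siI2 and siI3 shared 16 up and 56 down (1.8 and 10.7). After the GC and length correction the pairs shared 58 up and 23 down (4.3 and 2.5 for independent lists), 54 up and 63 down (14.3 and 17.1), and 19 up and 30 down (3.0 and 3.5). The covariance of fold changes was 0.234, 0.238 and 0.25 for these pairs, against 0.050, 0.051 and 0.051 in the simulation, and 0.126, 0.123 and 0.144 after the GC and length correction, against 0.042. The 3 controls cannot be split into sets of at least 2, so part of the excess may come from the shared controls. After the correction 9 genes up and 9 down were shared by all 3. The count of 28 was 1 without siC replicate 1, 750 without siC replicate 2 and 0 without siC replicate 3. It was 5, 16 and 6 without siI1 replicate 1, 2 or 3, 4, 330 and 5 without siI2 replicate 1, 2 or 3, and 5, 7 and 95 without siI3 replicate 1, 2 or 3.

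The fold changes of direct comparisons between knockdowns do not use siC. Their SE and p-values do, since all 12 libraries share the estimate of spread. The counts given below with 1 library left out never leave out a siC library. MMP2 was higher in siI1 than in siI3 by 4.13 on the log2 scale (SE 0.18, limma adjusted p = 8.1e-10, n = 3), at 284.7 ± 13.7 against 15.4 ± 2.53 FPM. ESM1 was lower in siI1 than in siI3 (-4.91, SE 0.28, limma adjusted p = 2.27e-08), as were SERPINB2 (-3.41), CCDC6 (-2.95), VGF (-2.71) and the hair keratin-associated KRTAP2-4 (-2.61). EFEMP1 (3.60), the red cell glycophorin GYPC (3.58), TUFT1 (3.58) and VSIR (3.57) were higher in siI1. The interferon list was higher in siI1 than in siI3 by a median of 0.96, with 12 of 29 members up and 0 down, and 18 up adjusted over the list alone (camera adjusted p = 7.03e-10; adjusted p = 0.0015 with an estimated correlation). PSMB9 (2.45), IFITM1 (2.29), IFI6 (1.96) and IRF1 (1.73) led it. ERK feedback genes (adjusted p = 4.36e-05; adjusted p = 0.167 with an estimated correlation) and inflammatory genes (adjusted p = 0.00135; adjusted p = 0.167 with an estimated correlation) were lower in siI1 than in siI3, and glycolysis and hypoxia genes higher (adjusted p = 0.00011; adjusted p = 0.203 with an estimated correlation). Histone genes were also called lower in siI1 (adjusted p = 0.000471; 0.78 with an estimated correlation). Called higher were invasion genes (0.00661; 0.109), TGF-beta targets (0.0225; 0.407), mesenchymal genes (0.025; 0.147) and ribosomal proteins (0.0429; 0.78), with the adjusted p at an estimated correlation given second. In all, 971 genes differed, 630 higher and 341 lower in siI1 (limma), and 1586 after the GC and length correction, with 950 called in both. The 971 became 546, 561 and 581 without siI1 replicate 1, 2 or 3, and 619, 560 and 1223 without siI3 replicate 1, 2 or 3.

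**Figure D3:**
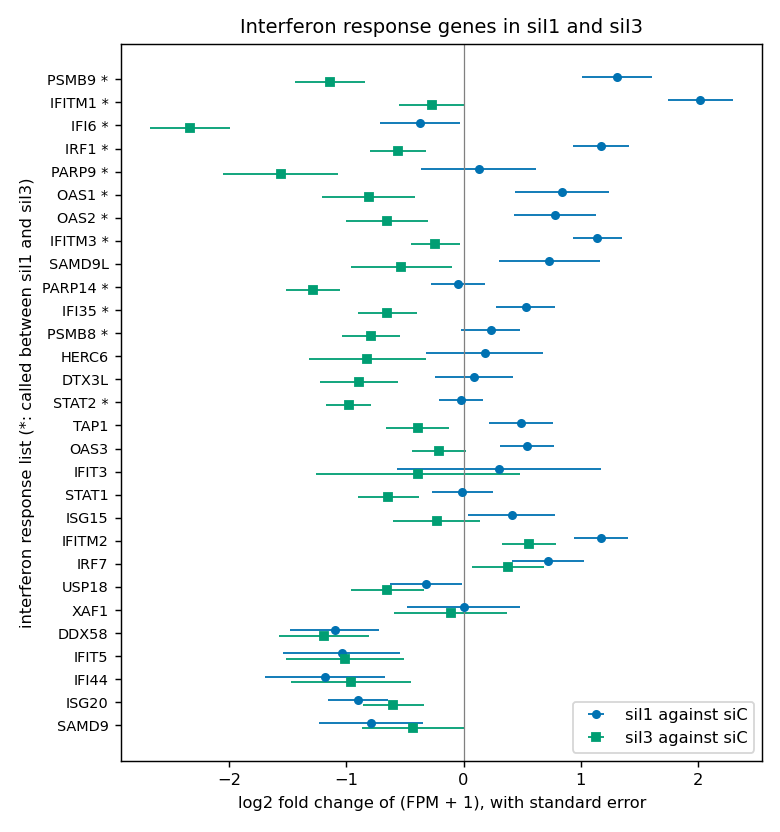
Log2 fold change of (FPM + 1) with its standard error (x axis) for the 29 measured genes of the interferon list (y axis), in siI1 and siI3 against siC (3 libraries per group). The 12 genes marked with an asterisk were called between siI1 and siI3, each of them higher in siI1.

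Against siC, 38 genes were called in opposite directions in siI1 and siI3, against 57.1 expected of independent lists. Both comparisons use siC, which favours calls in the same direction, so this expected number cannot tell whether 38 is an excess. The simulation gave 0, but it drew independent noise and could call few genes. After the GC and length correction there were 58, against 33.3 expected. The direct comparison called each of the 38, which follows largely from how they were chosen. Of these, 33 were up in siI1 and down in siI3, led by MMP2, TUFT1 and GYPC, and 5 were down in siI1 and up in siI3, led by ESM1. Among the 5 is the chemokine CXCL3 (-1.12 and 1.10), whose calls against siC were lost without siC replicate 1, siC replicate 3, any siI1 library, siI3 replicate 1 or siI3 replicate 2. These genes were chosen after their values were seen.

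**Figure D4:**
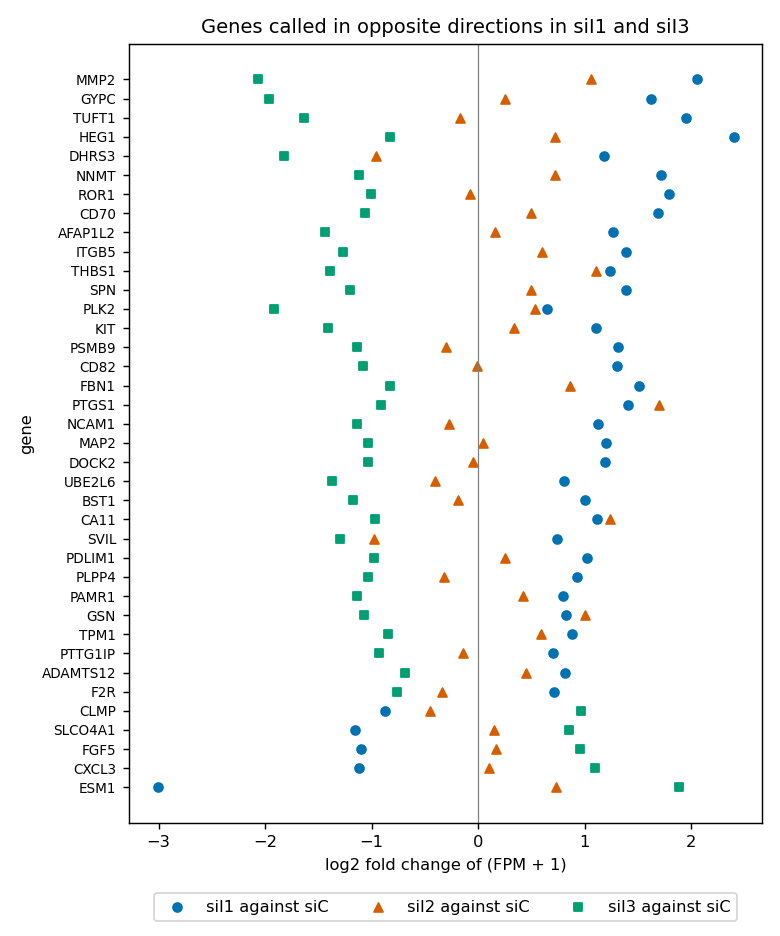
Log2 fold change of (FPM + 1) against siC (x axis) of the 38 genes (y axis) called in opposite directions in siI1 and siI3, with siI2 for comparison (3 libraries per group). MMP2 lies at 2.06 in siI1 and -2.07 in siI3, and ESM1 at -3.01 and 1.89.

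Between siI1 and siI2, 331 genes differed, 225 higher and 106 lower in siI1 (limma, n = 3), and 660 after the correction, with 320 called in both. RARRES3 (3.46), IGF2BP2 (2.70), the annexin ANXA8 (2.66), the transporter ABCC3 (2.61) and ADAMTS15 (2.50) were higher in siI1, and ESM1 (-3.74), CCDC6 (-2.44), the transporter SLC16A9 (-2.28), IGF2BP1 (-2.23) and ANGPT2 (-2.22) were lower. The interferon list was higher in siI1 than in siI2 by a median of 0.63 (camera adjusted p = 1.68e-05; adjusted p = 0.0113 with an estimated correlation), with 4 of 29 up and 1 down, and 11 up and 1 down adjusted over the list alone. Called higher in siI1 than in siI2 were glycolysis and hypoxia genes (adjusted p = 0.00031; 0.34 with an estimated correlation), YAP/TEAD and SRF targets (0.0154; 0.602), TGF-beta targets (0.0344; 0.517) and epithelial genes (0.0397; 0.267). Called lower were inflammatory genes (0.00015; 0.19), ERK feedback (0.0344; 0.517), the stress response (0.0344; 0.416) and histones (0.0344; 0.791). Between siI2 and siI3, 276 genes differed, 174 higher and 102 lower in siI2 (limma, n = 3), and 518 after the correction, with 270 called in both. MMP2 (3.13), PTGS1 (2.61), AC124067.2 (2.56), THBS1 (2.50) and PLK2 (2.45) were higher in siI2, and MMP3 (-3.73), IGF2BP2 (-2.90), VGF (-2.72), VAMP4 (-2.69) and the immediate early gene FOS (-2.47) were lower. The size of the MMP3 change is uncertain, since its siI2 mean lies under the floor. The interferon list was higher in siI2 than in siI3 by a median of 0.46 (camera adjusted p = 0.00318; adjusted p = 0.0576 with an estimated correlation). ERK feedback genes were called lower in siI2 than in siI3 (0.00795; 0.546 with an estimated correlation) and invasion genes higher (0.011; 0.0996). The named genes of the 3 direct comparisons kept their calls in each fit that left out 1 library and after the correction. The 331 became 127, 143 and 131 without siI1 replicate 1, 2 or 3, and 207, 225 and 243 without siI2 replicate 1, 2 or 3. The 276 became 112, 159 and 364 without siI2 replicate 1, 2 or 3, and 112, 123 and 410 without siI3 replicate 1, 2 or 3.

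The title of the study concerns miRNA-directed repression, so genes were compared by the miRNA sites in their 3' UTRs. Genes with a let-7 site (1271 genes) lay below those without (10088 genes) by a median of -0.084 in siI1, -0.056 in siI2 and -0.106 in siI3 on the log2 scale, and none of these differences passed. The limma camera test gave adjusted p = 0.485, 0.565 and 0.31 over the 72 tests. Of 17 families broadly expressed in human cells, 6, 7 and 6 were called down in siI1, siI2 and siI3, and 2, 2 and 0 were called up. The miR-26 family differed by -0.287, -0.243 and -0.253 and the miR-21 family by -0.268, -0.233 and -0.239. Of 7 tissue-restricted families that served as controls, 1, 2 and 1 were called down and 0 up, among them miR-216a, at -0.232, -0.203 and -0.229. After the GC and length correction 0 of the 72 tests were called (23 down and 4 up before), with differences between -0.051 and 0.096. Across genes, the log2 fold change correlated with the length of the 3' UTR at a Spearman's rho of -0.19, -0.18 and -0.18 in the 3 knockdowns, and at 0.03 in each after the correction.

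The authors' deposited table lists 457 genes below an FDR of 0.05 for siI1, 104 for siI2 and 266 for siI3, of which 441, 98 and 254 were also called here, each in the same direction. The authors' deposited table gives log2 fold changes of -1.99, -2.58 and -2.38 for IGF2BP1, IGF2BP2 and IGF2BP3 in their own knockdowns.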

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

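The tests of GC content, of miRNA sites, of separate preparation, of even background, of depth and of liver RNA, the GC test of the opposite genes and the splits of the libraries were chosen after the results were seen, and those of blood or neural RNA, of siI3 replicate 3 in the opposite genes and of siRNA off-target effects before.

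In 38 genes the effects of 2 knockdowns went opposite ways: 33 were up in siI1 and down in siI3, and 5 the reverse, with all 38 called directly (limma, median size 2.29 in log2), which their selection largely fixes. Independent lists of these sizes would give 57.1 such genes. Both comparisons use siC, which favours calls in the same direction, so 57.1 cannot tell whether 38 is an excess. Simulated unchanged groups with controls in common had fold changes that correlated at 0.5. After the GC and length correction the count was 58 against 33.3. The 38 include the gelatinase MMP2 (2.06 and -2.07), the transmembrane protein HEG1 (2.40 and -0.83), the integrin ITGB5 (1.39 and -1.27), the receptor kinase KIT (1.11 and -1.41) and the proteoglycan ESM1 (-3.01 and 1.89). After the GC and length correction 38 stayed called directly, with a median size of 2.24. The direct comparison held little GC trend to remove (Spearman's rho 0.03). A GC trend is thus argued against only for the difference between siI1 and siI3. Against siC, where rho was 0.6 and 0.55, 25 of the 38 were called in both knockdowns after the correction. A part from the GC trend stays open there. The direct calls did not rest on siI3 replicate 3, since 38 stayed called directly without that library. Their selection made this likely, and direct calls over all genes rose from 971 to 1223 without it. This test therefore cannot decide on a background in that library. Also open are different targets of the 2 proteins, as a hypothesis, and off-target effects of the siRNAs. The latter cannot be told apart from loss of the protein with 1 siRNA treatment per protein.

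Genes with a site of several miRNA families (23 of 72 tests called down, 4 called up) and AT-rich genes were lower in the knockdowns than in siC, the direction miRNA-directed repression would give after loss of an IGF2BP. A GC bias between libraries fits these values: slopes within siC spanned 0.48 (log2 per 10 points), more than the 0.39 between the mean of siC and of the knockdowns, and no site family was called after correction. That span rests on siC replicate 2, and the mean slopes still differed between siC and the knockdowns (two-sided exact permutation p = 0.0182 over 220 splits, n = 3 and 9). For miRNA repression, the broadly expressed families lay below the tissue-restricted ones by -0.065 at most (siI1), within the SD of 0.084 over the restricted families. The difference was -0.015 in siI2 and -0.011 in siI3. After the correction it was -0.014, 0.013 and 0 in siI1, siI2 and siI3. These values show no difference between the classes beyond that spread, and they leave miRNA repression open. Separate preparation of control and knockdown libraries cannot be told apart from the siRNA: 11 spike-ins differed in share, but they were selected for separating siC from the knockdowns.

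In siI3 replicate 3, 31369 genes had at least 1 read, against 21432 to 27071 in the other 11 libraries. Deeper sequencing is argued against, since 10 of the 11 other libraries had more reads. Genomic DNA or another even background may be the source: the share of reads on olfactory receptor genes was 2.31 times that of the highest other library, and 125 of these receptors had a read against 21 to 57. RNA of blood or neural cells as a large part of this library is argued against. Their summed markers reached 1.21 and 0.758 times the highest other library, under the criterion set for them. Smaller amounts are not excluded. The blood sum (6.02 FPM) lay above every other library (at most 4.96), and NEFL, at 22.9 FPM on average in siI3, weighed heavily in the neural sum (47 FPM). Liver markers reached 2.2 times, which met the first criterion set for them, but ALB, the most abundant liver mRNA, lay at 0.35 FPM (2 reads) below TF (4.43) and SERPINA1 (3.9), a criterion chosen after these values were seen; beyond RNA of other cells, no biological explanation was tested.

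The interferon response differed between 2 knockdowns under the same contrast: its median was higher in siI1 than in siI3 by 0.96 (camera adjusted p = 7.03e-10; adjusted p = 0.0015 with an estimated correlation; 29 genes). The ERCC spike-ins, data outside the comparisons, had shares of spike-in reads that differed between siC and the 9 knockdown libraries by at least 2-fold without overlap for 11 of 27 spike-ins, and ERCC-00002 took 37.3% of them in the knockdowns and 16% in siC.

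With 3 libraries against 3 there are 10 splits, so the share of splits with as many calls cannot be under 0.05. The real split gave 1128 genes for siI1 against siC and the highest other split 0 (1 of the 10 splits reached the real count), 1460 and 904 for siI3 against siC (1), 331 and 0 for siI1 against siI2 (1), and 971 and 0 for siI1 against siI3 (1). For siI2 against siC the real split gave 208 and the highest other 831 (2 of 10), the split that put siC replicates 1 and 3 with siI2 replicate 2, the 3 libraries with the lowest GC slopes (-0.46, -0.43 and -0.09). For siI2 against siI3 the real split gave 276 and the highest other 394 (2 of 10), the split that put siI2 replicates 1 and 2 with siI3 replicate 3. The split of 904 genes put siC replicates 1 and 3 with siI3 replicate 3, again the lowest slopes of its 6 libraries. After the GC and length correction these 3 comparisons gave 192 and 104, 518 and 527, and 938 and 0 genes in the real and the highest other split. These splits point to a structure of the libraries that does not follow the siRNA.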

How the results depend on the processing

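The main limma test on log2(FPM + 1), the other pseudocounts and the GC and length correction were chosen after the data were seen. edgeR's quasi-likelihood test on counts was the main test fixed in advance. Its use on recovered reads, as an alternative to limma, was also chosen after the data were seen. The other alternatives were planned. The knockdown of each target kept its direction and call under every alternative, and leaving out 1 library at a time gave -1.94 to -1.81 for IGF2BP1, -2.82 to -2.34 for IGF2BP2 and -2.37 to -1.89 for IGF2BP3. Counts of called genes moved most. Leaving out 1 library gave 268 to 2602 genes in siI1 against siC, 28 to 1572 in siI2, 89 to 2824 in siI3, 127 to 243 between siI1 and siI2, 546 to 1223 between siI1 and siI3, 112 to 410 between siI2 and siI3 and 0 to 750 in all 3 knockdowns. The low ends come without siC replicate 1 or 3, siI1 replicate 1, siI2 replicate 1 or siI3 replicate 1, and the high ends without siC replicate 2, siI2 replicate 3 or siI3 replicate 3. DESeq2 called 2014, 716 and 2296 genes in siI1, siI2 and siI3 against siC, 544 between siI1 and siI2, 557 between siI2 and siI3 and 161 in all 3 knockdowns. The edgeR exact test called 2722 in siI1, 554 between siI1 and siI2, 1620 between siI1 and siI3 and 61 in all 3. With no filter the counts were 481, 77 and 461 against siC, 172, 594 and 134 between knockdowns and 2 in all 3, where more genes enter the adjustment. With only the 6 libraries compared they were 2039 in siI1, 37 in siI2, 91 between siI2 and siI3 and 3 in all 3. Against a minimum change of 1.2-fold (glmTreat) they were 733, 80 and 591 against siC, 191 between siI1 and siI2, 175 between siI2 and siI3 and 6 in all 3, a stricter question by construction. With protein-coding genes only they were 359 in siI2 and 56 in all 3, and with a pseudocount of 4 they were 46 in all 3. With the GC and length correction they were 938 in siI3, 660, 1586 and 518 between knockdowns and 18 in all 3; also without siI3 replicate 3 they were 1987 between siI1 and siI3, 922 between siI2 and siI3 and 46 in all 3. Apart from the filter, the minimum change and the number of libraries, the cause was not tested.

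With the replicate number as a block the counts were 696, 95 and 745 against siC and 7 in all 3 knockdowns. Libraries with the same number correlated at -0.45 to 0.45 in their deviations from the group means, above 0.1 in 7 of 18 pairs, and 3 of 12 correlated best with their own number, so the numbers were not used as a pairing.

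Gene lists called were 0 in siI1, 0 in siI2 and 1 in siI3 with an estimated correlation, and the same 3 counts with the correction added. fry asks whether a list's genes move in 1 direction, without comparing them with other genes. It called 7 in siI3, among them let-7 targets and IGF2BP1-associated mRNAs, both down (fry adjusted p = 0.0417 each). The let-7 targets were not called by fry in siI1 or siI2 (0.195 and 0.179). The IGF2BP1-associated mRNAs were called down in siI1 (0.017) but not in siI2 (0.487). Among the lists that fry called down in siI2 were the interferon response (fry adjusted p = 0.00499) and the miRNA pathway machinery (0.0469). fry was not run after the GC and length correction. Leaving out 1 library gave 7 to 9 lists in siI1, 3 to 6 in siI2 and 4 to 4 in siI3. The let-7 difference ranged from -0.116 to -0.063 in siI1, -0.097 to -0.009 in siI2 and -0.132 to -0.077 in siI3 over these fits. Its sign reversed, without passing the test, when genes were matched on 3' UTR length (0.032, 0.023 and 0.002) and after the GC and length correction in siI1 (0.003) and siI2 (0.01). Of 5594 alternative values of the named genes, 4677 kept their side of the threshold, 916 lost the call, 1 gained it and 0 reversed. Losses were most frequent when 1 library was left out (545 of 1584), with no filter (78 of 264), under the minimum change (56 of 264), after the GC and length correction (52 of 257) and with the block (47 of 264). With 3 libraries per group, at 3299360 to 11304060 reads each, simulated 1.5-fold changes were recovered in 1.5% of genes; the share due to depth was not tested.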

Other observations

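The spike-in test was chosen after the result was seen, and the values in the other paragraph come from lists fixed in advance.

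Of 9 endothelial markers, 2 passed the filter in these ovarian cancer cells, and the other 7 reached at most 3.15 FPM (VWF). The receptor TIE1 reached 302 FPM and averaged 163 FPM in siC and 167, 218 and 236 FPM in siI1, siI2 and siI3, and the junction protein CDH5 averaged 60.5 FPM in siC and 140, 114 and 101 FPM in the knockdowns (n = 3 each). CDH5 was called in all 3 knockdowns, at 1.21, 0.91 and 0.74 on the log2 scale, and after the GC and length correction at 1.03, 0.81 and 0.63 (limma). Its call in siI2 was lost without siC replicate 1, siC replicate 3 or siI2 replicate 1, and in siI3 without siC replicate 1, siC replicate 3, siI3 replicate 1 or siI3 replicate 2, while that in siI1 held in each fit. The highest marker was CD4 at 2.39 FPM for blood (0 of 15 measured above the filter) and SERPINA1 at 4.45 FPM for liver (1 of 15). Of the neural markers 5 of 15 passed the filter, the highest of them NEFL, which averaged 27.8 FPM in siC and 32.9, 44.5 and 22.9 FPM in siI1, siI2 and siI3 and reached 48.3 FPM. In siI3, 18 of 75 cytosolic ribosomal protein genes were called down and 0 up (limma; list not called), 8 of them also after correction, while 1 and 0 were called in siI1 and siI2. RPS27A was lower in siI3 by -2.01 (corrected -1.54, lost without siC replicate 1) and RPL24 by -1.39 (corrected -0.94, lost without siC replicate 1, siC replicate 3 or siI3 replicate 2). The difference between knockdowns in these genes was called for 2 of 75 in siI1 against siI3, 5 after correction, and 0 of 75 in siI2 against siI3. As a list they were called higher in siI1 than in siI3 (camera adjusted p = 0.0429; adjusted p = 0.78 with an estimated correlation; 0.106 after correction).

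Of 27 spike-ins, 7 had lower and 6 higher shares in the knockdowns than in siC without overlap, and 14 overlapped. Of those that differed at least 2-fold, the 7 lower ones had a median of -2.18 in log2 share (-2.83 to -1.6) and the 4 higher ones of 1.24. Another commercial spike-in mix in siC than in the knockdowns could give such shifts, but it cannot be told apart from other causes, because the 2-fold selection bounds the higher values and the other positive values run from 0.19 to 1.07. The medians of -2.18 and 1.24 lay near the design steps of the commercial mixes, -2 and 1 in log2. The labels name no mix, and which spike-in belongs to which step was not compared here.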
